A study of Homo sapiens with 4 samples.

How the data were processed

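RNA of HSC-3 cells carrying a control or an MMP8 lentiviral vector, selected with puromycin and grown with hydrocortisone and serum, was collected from intact and from wounded cell layers. Per the labels, RNA of 3 wells was pooled in equal amounts for each of the 4 arrays and turned into biotinylated cRNA with a 3′ in vitro transcription kit. The description of the MMP-8 line names a red fluorescent label and that of the control line does not. The time between wounding and harvest is not given in the sources used here.

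The deposited values are linear probe set intensity values of the Affymetrix HG-U133 Plus 2.0 array, summarised by the authors. The method of summarisation, background correction and normalization is not given in the sources used here. The 4 arrays had nearly equal medians, and between 1.98% and 2.22% of the values on each array were exactly 1, so the lowest values carry little information. As the table is linear, log2(intensity + 16) was used, the rule fixed for that case before the data were examined. The constant shrinks the differences of dim genes.

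Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers (41037 updated or matched) using the RefSeq gene table of assembly GRCh38.p14. Of 54613 probe sets, 41091 had 1 symbol, 1801 several and 11721 none, and probe sets with several or none were not named. Each of 19775 genes was represented by its probe set of highest mean. A gene was compared if its highest value reached the median of all values (intensity 23.53), which left 13640 genes.

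Samples were grouped by the line and state in their labels. Single differences between 2 arrays were counted at 2-fold or more, with no test. Over both states or both lines, limma (version 3.58.1 in R 4.3.3) was fitted with additive terms for line and state, moderated with an intensity trend, and called at a Benjamini-Hochberg adjusted p under 0.05. This fit has 1 residual degree of freedom per gene, which is the difference between the responses. With the trend the prior degrees of freedom were infinite, so the standard error of a gene comes from genes of like intensity and not from its own residual. Without the trend they were 2.63. The p-values therefore do not reflect how alike the 2 differences of a single gene are. They assume that wounding acts alike in both lines and cover neither a second transduction nor a second pool. As a measure of noise, the crossed split of the arrays was counted in the same way as the effects of line and state. Its differences are the residuals that set the standard errors, so it is not an independent rate of false calls.

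The rule for named genes was fixed before the data were examined. It takes MMP8, TGFB1 and VEGFC, in each direction the 10 genes of largest mean difference among those at least 2-fold different in both contrasts, the 5 largest differences of response in each direction, and up to 4 members of each list for each effect. Some further members of lists are given as examples and were chosen after their values were seen. The 22 gene lists were also fixed before. For each list the percentile of its median among 10000 random lists of the same size, drawn within 20 bins of mean intensity, describes these arrays. Members called were counted over all genes and adjusted over the list alone.

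The fit was tested on simulated data for the MMP-8 effect with 13640 genes and 200 changed genes. It recovered 74.6% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes with normal noise, and 6.3% of its calls were false. With noise resampled from the crossed split it recovered 76.1%, 91.8% and 99.2%, and 9.92% of its calls were false. These are means of 2 runs. The simulated noise depended on intensity alone, as the fit with the trend assumes, and no wounding effect or difference of response was planted. The false shares therefore do not carry over to the calls in the real data.

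Alternatives were quantile normalization, median centring, cyclic loess, the median over the probe sets of a gene, leaving out probe sets marked as possibly cross-hybridizing, added constants of 1 and 64, no filter, a filter at the 75th percentile (intensity 156.9), a 1.5-fold threshold, the fit without trend, and 2-fold in both contrasts without a test. After seeing the data, a minimum intensity of 100 and a call that also needs 1.5-fold in both contrasts were added. A further 4 gene lists, for ribosome biogenesis, glucocorticoid-induced genes, FOXO targets and ERK pathway output, were chosen after the genes that changed most with wounding had been seen.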

Results

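Gene expression was measured in HSC-3, a human oral tongue squamous carcinoma line, after lentiviral transduction with a vector carrying MMP8 or with a vector carrying a non-coding sequence. MMP8 encodes the collagenase MMP-8 (neutrophil collagenase). Each transduced line was harvested from intact cell layers (stationary cells) and from wounded layers (migrating cells), which gave 4 groups with 1 array each. RNA of 3 wells was pooled for each array, so no difference between 2 arrays has a replicate check, and the number of arrays limits the precision. Each array held 54613 probe sets, and their median intensities were 23.8 in stationary control cells, 23.5 in stationary MMP-8 cells, 23.3 in migrating control cells and 23.7 in migrating MMP-8 cells. After the entry filter 13640 genes were compared, of which 4383 (32.1%) did not reach an intensity of 100 on any array. Unless stated otherwise, the value given after a gene is the mean of its 2 differences on the log2(intensity + 16) scale. The words "rose" and "fell" are used for an adjusted p under 0.05 in limma's additive fit over all 4 arrays. Each standard error after ± comes from genes of like intensity. It does not show how far apart the 2 differences of a gene lie.

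The transduced gene and the growth factors named in the series title were examined first. Neither probe set of MMP8 reached the entry intensity of 23.53 on any array. One read 5.37 in stationary control cells, 10.0 in stationary MMP-8 cells, 9.20 in migrating control cells and 8.09 in migrating MMP-8 cells, and the other read 11.7, 7.28, 14.7 and 6.99 in the same order. The 2 probe sets differed in sign between the stationary lines (0.28 and -0.25), so the arrays did not check the labels, and whether the vector carries the part of the transcript that is probed is not given in the sources used here. "MMP-8 line" therefore means the cells labelled so. VEGFC, a growth factor of lymphatic vessels, fell by 0.50 ± 0.08 (SE) in the MMP-8 line, a 1.41-fold lower level. Its intensity was 669 against 420 in stationary control and MMP-8 cells and 810 against 636 in migrating cells. TGFB1, the gene of the ligand TGF-β1, differed by 0.01 ± 0.16 between the lines (adjusted p = 0.989 in limma). It fell by 0.57 ± 0.16 with wounding, from 77.9 to 47.3 in control cells and from 78.6 to 47.5 in MMP-8 cells, whereas VEGFC rose by 0.43 ± 0.08.

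The comparison of the lines asked which genes differ with the MMP-8 vector. Keratinocyte differentiation genes were higher in the MMP-8 line in both states, and MMP1, the interstitial collagenase, and the adhesion molecule L1CAM were lower in both. Among the genes at least 2-fold different in both states, the gap junction gene GJB6 had the largest mean difference, with intensities of 265 and 1437 in stationary control and MMP-8 cells and 363 and 1599 in migrating cells, a 4.69-fold rise (2.23 ± 0.08). The chemokine gene CXCL14 rose by 1.70 ± 0.12, the mean of 2.07 in stationary and 1.33 in migrating cells. KRT4, a keratin gene of mucosal epithelium, and KRTDAP, which encodes a keratinocyte differentiation-associated protein, also rose (1.93 ± 0.24 and 1.84 ± 0.24). MMP1 fell by 1.32 ± 0.07, from 1921 to 723 in stationary cells and from 2583 to 1081 in migrating cells. L1CAM fell by 1.30 ± 0.08, from 1116 to 420 and from 865 to 361.

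In stationary cells 94 genes differed at least 2-fold between the lines, 65 higher and 29 lower in the MMP-8 line. In migrating cells 106 did, 64 higher and 42 lower. These counts carry no test. In both states 18 genes were at least 2-fold higher and 6 at least 2-fold lower. These 24 genes also passed the additive fit, which adds little, since 40 of the 41 genes with a mean difference of at least 2-fold did. Among the higher genes were also FAM133A (1.67), KRT13 (1.58), the cornified envelope gene SPRR1B (1.55), the galactosyltransferase gene UGT8 (1.51, with its other probe set at 0.78), TUSC1 (1.49) and the teneurin gene TENM2 (1.49). KRT4, KRTDAP and FAM133A read below 10 on both control arrays and between 59.1 and 78.9 in the MMP-8 line, so their folds and their rank depend on the added constant. The other lower genes were the pentraxin gene PTX3 (-1.33), TMEM71 (-1.29), the nicotinamide N-methyltransferase gene NNMT (-1.22) and GPAT3 (-1.22), an acyltransferase of triglyceride synthesis.

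**Figure D1:**
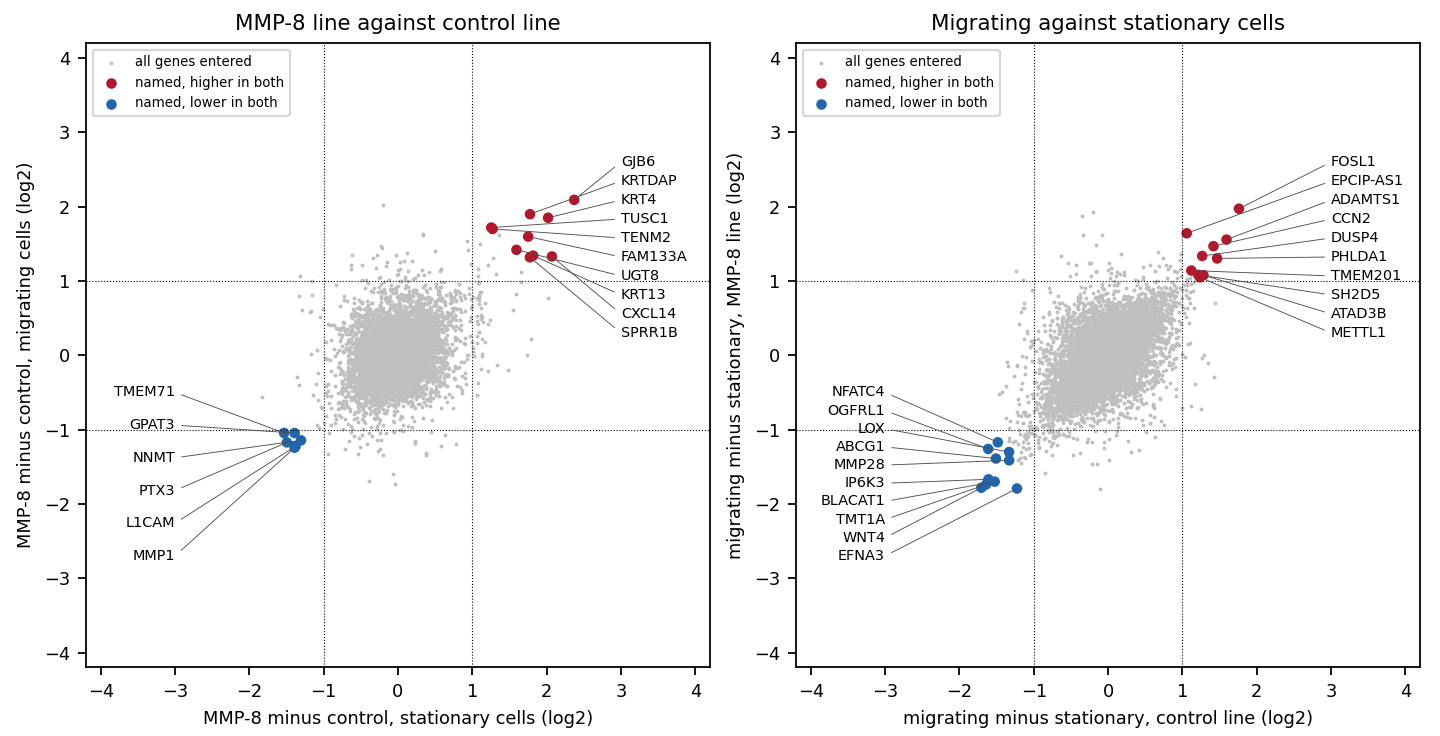
Differences on the log2(intensity + 16) scale of the 13640 genes entered, with the MMP-8 minus control difference in stationary (x) and migrating (y) cells on the left and the migrating minus stationary difference in the control (x) and MMP-8 (y) lines on the right. Coloured points are the named genes that differed at least 2-fold in the same direction in both contrasts, dotted lines mark 2-fold, and 1 gene in each panel lies outside the axes.

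The additive fit called 1438 genes between the lines, of which 685 rose and 753 fell, and 40 of them had a mean difference of at least 2-fold. The 2 differences of a gene had the same sign for 1422 of the calls. The only measure of error in this fit is how alike the 2 differences are over genes of like intensity, not for the gene itself, and without that trend of the variance with intensity limma called 0 genes at an adjusted p under 0.05 (1968 at an unadjusted p under 0.05, and 2946 with the trend). The crossed split of the arrays sets stationary control with migrating MMP-8 cells against the other pair. It reached the same distance from 0, in standard errors, for 165 genes, or 11.5% of the number of calls. The crossed differences themselves set these standard errors, so this share is not an independent rate of false calls.

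Of the 22 gene lists fixed in advance, 10 had a median line difference outside the central 95% of 10000 random lists matched on expression. If members moved independently, 1.1 lists would be expected. Genes of a list can move together and some stand in several lists, so the excess does not measure replication. Genes of keratinocyte differentiation had a median of 0.48 (percentile 100), with 10 of 21 measured members rising, 0 falling and 11 not passing. Adjusted over the list alone, 13 rose. KLK10, a kallikrein protease gene, rose by 1.30 ± 0.07, from 996 to 2150 in stationary cells and from 723 to 2077 in migrating cells, and S100A8, a calcium-binding protein gene of stressed keratinocytes, rose by 1.21 ± 0.11. The suprabasal gene KRT10 (0.00) and the envelope precursor gene IVL (-0.11) did not pass. In the list of urokinase, kallikrein and ADAM proteases, whose median of 0.04 lay at percentile 93, 6 of 20 members rose and 3 fell. The members that rose included 3 kallikrein genes shared with the keratinocyte list, KLK10, KLK5 (0.83) and KLK7 (0.65), besides KLK11 (1.18), and PLAT, tissue plasminogen activator, fell by 0.25.

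Immediate early genes, which respond to growth factors and stress, had a median of 0.27 (percentile 100). Of 19 members 9 rose and 1 fell, and 13 rose and 2 fell adjusted over the list alone. FOS rose by 1.39 ± 0.12, the mean of 2.01 in stationary cells (from 76.9 to 359) and 0.77 in migrating cells. EGR1 rose by 1.20 ± 0.06, the mean of 1.59 and 0.82 in the same order. The ERK phosphatase genes DUSP6 (0.83) and DUSP5 (0.70) rose, and FOSL1 fell by 0.41. The list of EGFR ligands and ERBB receptors, which also holds ERK feedback genes, had a median of 0.14 (percentile 99.8), or 0.07 in stationary and 0.23 in migrating cells. Of 12 members 3 rose, the ligand gene EREG (0.56) and the feedback genes DUSP6, already given, and SPRY2 (0.37), and 1 fell. The receptor genes EGFR, ERBB2 and ERBB3 and the ligand genes HBEGF, TGFA and BTC did not pass. The falling member was NRG1 (-0.66), whose other 3 probe sets read 0.62, 0.19 and 0.32. The median of epithelial junction and keratin genes was 0.06 over the mean differences (percentile 99.3), while it was 0.04 in stationary and -0.01 in migrating cells. Of 24 members 3 rose, namely PKP1 (0.36, other probe set at 0.12), KRT19 (0.28) and GRHL2 (0.27), and 3 fell, namely KRT8 (-0.44), EPCAM (-0.39) and KRT18 (-0.26).

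The other 6 lists outside the random range lay below it. Interferon response genes had a median of -0.17 (percentile 0, 0 rising and 4 falling of 21), which was -0.20 in stationary and -0.08 in migrating cells. Among them were ISG15 at -0.55, OAS2 at -0.38 (other probe sets at -0.21 and 0.11) and IFIT1 at -0.35. Sterol synthesis genes had a median of -0.19 (percentile 0, 0 rising and 6 falling of 12), with INSIG1 at -0.49 and HMGCS1 at -0.43, and 9 fell adjusted over the list alone. Inflammatory cytokines and NF-κB targets had a median of -0.13 (percentile 0.49, 0 rising and 4 falling of 18). It was -0.32 in stationary and -0.05 in migrating cells, a difference that was not tested. TNFAIP3 fell by 0.71, SOD2 by 0.61, TNF by 0.59 and CXCL8 by 0.52. Mesenchymal markers had a median of -0.14 (percentile 0.475, 0 rising and 3 falling of 11), and the falling members were the transcription factor gene TWIST1 (-0.55), VIM (-0.17) and SPARC (-0.14). Integrins and basement membrane genes had a median of -0.12 (percentile 0.2) with 1 rising and 1 falling of 18, LAMC1 (-0.27) falling and ITGB8 (0.37) rising, although 2 of the other 3 ITGB8 probe sets were lower in the MMP-8 line (-0.27 and -0.33). The VEGF family and angiogenic factors had a median of -0.12 (percentile 1.84), and VEGFC was the 1 member of 15 that fell, with 0 rising.

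Matrix metalloproteinases and their inhibitors had a median inside the random range (-0.05, percentile 15.8). Of 16 members 5 fell, namely MMP1, the stromelysin genes MMP3 (-0.84) and MMP10 (-0.55), the inhibitor gene TIMP2 (-0.43) and MMP2 (-0.30), and 1 rose, the gelatinase gene MMP9 (0.58). TGF-β ligands, receptors and SMADs (0.01, percentile 55.6) had 2 rising and 1 falling of 21. LTBP1, which binds latent TGF-β, rose by 0.81 ± 0.11, LTBP2 rose by 0.29 and INHBA fell by 0.29. TGF-β response genes (-0.02, percentile 40.1) had 1 rising and 2 falling of 16. TGM2 was at -0.36, with other probe sets at 0.06 and -0.56, and the target CCN2 differed by -0.01. The remaining lists also lay inside the range. YAP and serum response targets (percentile 26.8) had 1 rising and 1 falling of 14, and cell cycle genes (percentile 37.2) had 3 rising, CCNE1 (0.60) among them, and 1 falling of 26. Hypoxia and glycolysis genes (percentile 28.7) had 4 rising and 0 falling of 19, with SLC2A3 at 0.61 (other probe sets at 0.27 and 0.41) and NDRG1 at 0.46. Genes of the unfolded protein and amino acid stress response (percentile 94.8) had 5 rising and 0 falling of 19, with ASNS at 0.36, and p53 targets (percentile 82.8) had 2 rising and 0 falling of 12. Markers of other cell types stayed inside the range. Fibroblast markers (percentile 95.8) had FAP rising (0.76) and FBN1 falling (-0.87) among 8, while 0 of 7 leukocyte markers (percentile 57.2) and 0 of 3 endothelial markers (percentile 51.1) passed.

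**Figure D2:**
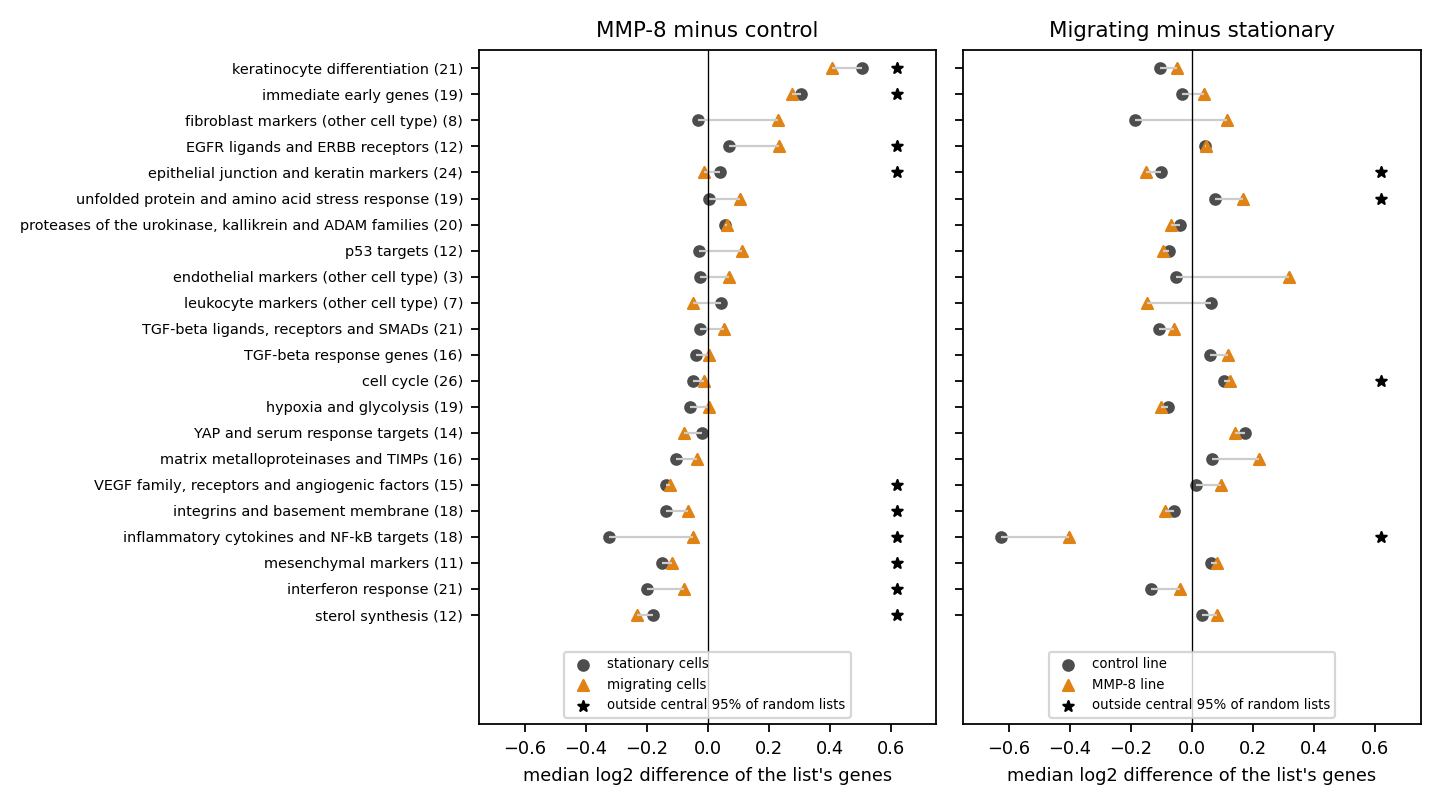
Median log2 difference of the members of each of the 22 gene lists (number of measured members in parentheses), as MMP-8 minus control on the left and migrating minus stationary on the right, with 1 point for each pair of arrays. Stars mark the 10 lists (left) and 4 lists (right) whose median over the mean differences lay outside the central 95% of random lists, with keratinocyte differentiation highest on the left and inflammatory genes lowest on the right.

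The comparison of wounded with intact layers asked which genes differ in wounded layers, labelled migrating. A difference between the layers is not assigned here to the cells that moved. The genes FOSL1, ADAMTS1 and CCN2 were higher after wounding in both lines, and 11 of 18 inflammatory genes and 10 of 24 epithelial junction and keratin genes fell. FOSL1, an AP-1 transcription factor gene, rose 3.65-fold (1.87 ± 0.09), from 195 to 699 in control cells and from 132 to 563 in MMP-8 cells. The protease gene ADAMTS1 rose by 1.57 ± 0.12, CCN2 (connective tissue growth factor) by 1.44 ± 0.13, and the ERK phosphatase gene DUSP4 by 1.30 ± 0.09. The ligand gene WNT4 fell 3.35-fold (-1.74 ± 0.16), from 132 to 29.4 and from 119 to 23.3, and LOX, the collagen cross-linking lysyl oxidase gene, fell by 1.32 ± 0.12.

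In the control line 138 genes differed at least 2-fold with wounding, 44 higher and 94 lower in migrating cells, and in the MMP-8 line 163 did, 63 higher and 100 lower. In both lines 14 genes were at least 2-fold higher and 39 at least 2-fold lower. These 53 genes passed the additive fit, which adds little, since all 88 genes with a mean difference of at least 2-fold did. Other higher genes were PHLDA1 (1.38), EPCIP-AS1 (1.35), ATAD3B (1.18), SH2D5 (1.15), the transfer RNA methyltransferase gene METTL1 (1.14) and TMEM201 (1.13). The other probe sets of 3 of the higher genes read less, at 0.26 for ADAMTS1, 0.41 for ATAD3B and 0.36 for TMEM201, while of the other 4 of PHLDA1, 3 read less (0.51, 0.41 and 0.24) and 1 read more. EPCIP-AS1 read 7.20 and 4.14 on the stationary arrays, below the entry intensity. Other lower genes were IP6K3 (-1.64), BLACAT1 (-1.61), the ephrin gene EFNA3 (-1.51), OGFRL1 (-1.44, others at -0.58 and -0.72) and NFATC4 (-1.33, others at -0.15 and -0.52). The other probe set of LOX was at -0.69. On the migrating arrays IP6K3 (19.5 and 17.0) and BLACAT1 (18.1 and 11.7) read below the entry intensity, as WNT4 and ABCG1 did on 1 of them, so the size of these falls and their rank depend on the added constant. Probe sets differed in sign for 3 of the 10 lower genes named. TMT1A was at -1.69 and its other probe set at 0.19, the cholesterol transporter gene ABCG1 at -1.45 and 0.02, and MMP28 at -1.37 with other probe sets at -1.34, -1.01, -0.04 and 0.14.

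The additive fit called 4263 genes for wounding, 2001 rising and 2262 falling, of which 88 had a mean difference of at least 2-fold and 4234 had both differences of the same sign. The crossed split reached the same distance from 0 for 357 genes (8.37% of the number of calls), with the same limit as for the lines. Without the variance trend limma called 0 genes at an adjusted p under 0.05 (4015 at an unadjusted p under 0.05, and 5302 with the trend).

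Of the 22 lists, 4 had a median wounding difference outside the central 95% of random lists. If members moved independently, 1.1 would be expected. Inflammatory cytokines and NF-κB targets had a median of -0.50 (percentile 0). Of 18 members 11 fell and 1 rose, the cyclooxygenase gene PTGS2 (0.35). The epithelial cytokine gene TSLP fell by 1.06 ± 0.15, the NF-κB inhibitor gene TNFAIP3 by 0.99 ± 0.08 (from 1224 to 514 in control cells and from 629 to 364 in MMP-8 cells), NFKBIA by 0.87, TNF by 0.87, CCL20 by 0.78 and IL1B by 0.69. Epithelial junction and keratin genes had a median of -0.11 (percentile 0.78), with 4 rising and 10 falling of 24 and 12 falling adjusted over the list alone. CLDN1, a tight junction gene, fell by 0.98 ± 0.07, the desmosomal gene DSG3 by 0.79 and KRT15 by 0.66, while KRT18 (0.41), KRT8 (0.30), the desmosomal gene PKP3 (0.26) and GRHL2 (0.19) rose. The other 10 members, CDH1, TJP1 and OCLN among them, did not pass.

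Cell cycle genes had a median of 0.12 (percentile 99.8), and the members moved in both directions. Of 26 members 13 rose, including the cyclin gene CCNE2 (0.85), the helicase genes MCM5 (0.65) and MCM2 (0.52), E2F1 (0.63) and the mitotic gene CDC20 (0.23). Other probe sets read 0.22 for CCNE2, 0.535 for MCM5 and 0.85 for E2F1. Another 9 fell, including TOP2A (-0.40), BUB1 (-0.36), CCNB2 (-0.33), MKI67 (-0.32) and CDK1 (-0.31). Genes of the unfolded protein and amino acid stress response had a median of 0.17 (percentile 99.7), with 9 rising and 3 falling of 19. XBP1 (0.60), ASNS (0.57) and ATF5 (0.56) rose, and DDIT4 (-0.74) and CEBPB (-0.60) fell.

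The other lists lay inside the random range. Metalloproteinases and inhibitors (percentile 96.4) had 5 rising and 3 falling of 16, with MMP3 (0.87), MMP1 (0.50) and MMP10 (0.49) rising. TGF-β ligands, receptors and SMADs (percentile 4.28) had 1 rising and 7 falling of 21, with SMAD3 at -0.72, although its other probe sets read 0.04, -0.48 and -0.23. TGF-β response genes (percentile 86.2) had 4 rising and 4 falling of 16, with CCN2 and PMEPA1 (0.85) rising and BHLHE40 (-0.53) falling. The other probe set of BHLHE40 was at 0.05. YAP and serum response targets (percentile 90.6) had 5 rising and 1 falling of 14, CCN1 (0.56) among the former. Immediate early genes (percentile 76.4) had 6 rising and 6 falling of 19, with DUSP5 (1.12) rising and DUSP1 (-1.20) and FOS (-0.84) falling, although FOS differed by -0.22 in the control line and by -1.46 in the MMP-8 line. The VEGF list (percentile 95.1) had 3 rising and 3 falling of 15, mesenchymal markers (percentile 95) had 3 and 1 of 11, and integrins and basement membrane genes (percentile 5.79) had 3 and 7 of 18, with LAMB1 at -0.64. Urokinase, kallikrein and ADAM proteases (percentile 11.9) had 3 rising and 7 falling of 20, with the urokinase receptor gene PLAUR (0.74, other probe set at 0.33) rising and PLAT (-0.72) falling. Hypoxia genes (percentile 14.2) had 3 and 6 of 19, p53 targets (percentile 37.2) 1 and 4 of 12, interferon genes (percentile 21) 1 and 3 of 21, sterol genes (percentile 74.6) 5 and 3 of 12, EGFR ligands and receptors (percentile 78.5) 3 and 1 of 12, and keratinocyte differentiation genes (percentile 4.21) 1 and 3 of 21. Among markers of other cell types, 1 of 7 leukocyte markers passed, CD14 (-0.95, list percentile 50), 1 of 8 fibroblast markers did, COL1A1 (-0.50, list percentile 38.4, with other probe sets at -0.51 and 0.15), and 0 of 3 endothelial markers did (percentile 89.1).

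**Figure D3:**
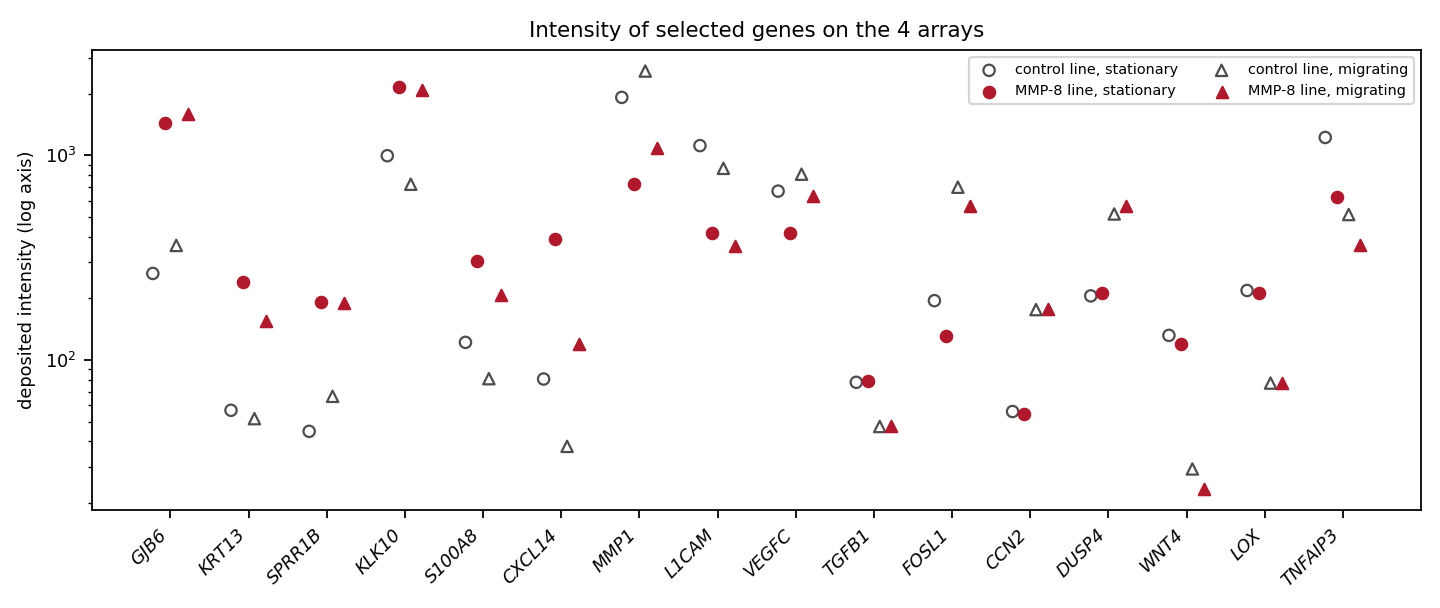
Deposited intensity (log axis) of 16 genes in the control line (open) and the MMP-8 line (filled), in stationary (circles) and migrating (triangles) cells, with 1 array per symbol. GJB6 lies between 265 and 363 in the control line and between 1437 and 1599 in the MMP-8 line, and FOSL1 lies between 132 and 195 in stationary and between 563 and 699 in migrating cells.

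The crossed design also asks whether wounding acts alike in both lines. Across the 13640 genes the wounding differences of the 2 lines had a Pearson correlation of 0.564, and the line differences of the 2 states, which share no array, one of 0.334, where genes are not independent replicates. The response to wounding differed at least 2-fold between the lines for 190 genes, higher in the MMP-8 line for 126 and lower for 64, and 181 of them (95.3%) stayed under an intensity of 100 on all arrays. FOS (-1.24) was among those that did not. GPR146 differed most, with 514 in stationary control cells and 4.91, 6.76 and 2.79 on the other arrays, so that its wounding differences were -4.54 in the control line and -0.15 in the MMP-8 line. It rests on 1 array, with no other probe set above the entry intensity, although the additive fit called it for both effects. The next genes with a higher response in the MMP-8 line were PDE6G (2.38), LAMA2 (2.23), SNORA17B (2.16) and SIGLEC7 (2.13), and those with a lower response were FGF18 (-1.97), TPTE2P5 (-1.80), SLC6A13 (-1.73), PHC1 (-1.72) and LOC441081 (-1.71). Apart from PHC1, all of these genes read below the entry intensity on at least 1 array, so the sizes and their rank depend on the added constant. No test of these differences was possible with 1 array per group. At a mean difference of at least 2-fold the split by line held 41 genes, the split by state 88 and the crossed split 5. At a mean difference of at least 0.5 these numbers were 491, 1150 and 190, and among the 9257 genes that reached an intensity of 100 they were 220, 788 and 9.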

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

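The tests of cell density, of dim probe sets and of other probe sets given here were chosen after related values had been seen.

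Of the 10 genes named for their difference of response, the 5 largest in each direction, 9 moved in opposite directions in the 2 lines with wounding, and none of these differences was tested. The wounding difference in the MMP-8 line exceeded that in the control line by 2.38 for PDE6G, 2.23 for LAMA2, 2.16 for SNORA17B and 2.13 for SIGLEC7. The same quantity was -1.97 for FGF18, -1.80 for TPTE2P5, -1.73 for SLC6A13, -1.72 for PHC1 and -1.71 for LOC441081. PHC1 read 90.6 in stationary control cells and between 270 and 337 on the other 3 arrays, while PDE6G, SNORA17B, SIGLEC7, FGF18, TPTE2P5, SLC6A13 and LOC441081 stayed under an intensity of 100 on all arrays. Every one of the 9 except PHC1 read below the entry intensity on at least 1 array, so the sizes depend on the added constant. Other probe sets read 0.06 for PHC1, 0.87 for FGF18, and 0.16 and -0.03 for LAMA2.

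Probe sets with no symbol or several were not part of the comparisons of genes. Of 5278 such probe sets above the entry intensity, 10 were at least 2-fold higher and 6 at least 2-fold lower with wounding in both lines. Between the lines 3 were at least 2-fold higher and 1 at least 2-fold lower in the MMP-8 line in both states. Opposite 2-fold responses of the 2 lines were seen for 0 of them.

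The first pattern weighed is the higher level of keratinocyte differentiation genes in the MMP-8 line. Noise of dim probe sets is argued against, since the whole list was set against random lists of equally dim genes, and the 5 members whose mean over the control arrays reached the 75th percentile of all values had a median difference of 0.30, at percentile 100 of random lists of such genes. The size of the change of the dimmer members stays uncertain. A lower density of the control cultures that acts like wounding would turn the wounding genes the other way. Across the 4263 genes called for wounding the line and wounding differences correlated at 0.14. A density effect of this kind is thus argued against as the whole cause, although the list's own wounding median was -0.13 (percentile 4.21). A density effect that acts otherwise than wounding was not tested. An effect of MMP-8 and a difference between 2 separately made lines, through transduction, selection or the fluorescent label, cannot be told apart, because there was 1 line per vector. The pattern may therefore belong to the line and not to the enzyme.

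The second pattern is the set of 190 genes whose wounding response differed at least 2-fold between the lines. For the 20 of them with another probe set above the entry intensity, the other probe set had the same sign for 7, or 35% (exact 95% interval 15.4% to 59.2%). The same share was 82.2% for 157 genes differing between the lines and 82.7% for 509 genes differing with wounding, each at a mean difference of at least 0.5. These genes come from brighter sets. Of all 491 and 1150 genes at that difference, 55.2% and 31.5% stayed under an intensity of 100, against 95.3% of the 190. The shares among the genes with another probe set were not counted. For these 20 genes noise of dim probe sets is a candidate explanation. A response that depends on the line is not excluded, since a dim second probe set could miss it. Only 2 of the 20 had both probe sets at an intensity of 100 or more on an array, with the same sign for 0 of them (upper 95% bound 84.2%), so for these 20 genes it cannot be told apart from noise. The other 170 genes have no second probe set above the entry intensity, and for them noise and a line-dependent response cannot be told apart with 1 array per group.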

How the results depend on the processing

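The minimum intensity of 100 and the rule of 1.5-fold in both contrasts were chosen after seeing the data; the other alternatives were fixed before. Counts of genes moved by more than 1.5 times as follows, with the order stationary, migrating, control line, MMP-8 line, difference of responses. An added constant of 1 gave 361, 424, 532, 487 and 717 genes, and one of 64 gave 24, 10, 35, 30 and 8. A 1.5-fold threshold gave 523, 622, 1060, 1052 and 913. The filter at the 75th percentile, which keeps 8205 genes against 13640, gave 29, 20, 67, 69 and 6, and no filter gave 381 differences of response. With the median over probe sets, wounding in the MMP-8 line gave 108. For the MMP-8 effect, the median over probe sets gave 770 calls, no filter 537, and 2-fold in both contrasts without a test 24. The fit without the trend gave 0 calls for the MMP-8 effect and 0 for wounding, with smallest adjusted p of 0.26 and 0.081 in limma. Wounding gave 53 genes at 2-fold in both contrasts. Adding 1.5-fold in both contrasts left 116 genes for the MMP-8 effect (62.9% higher, against 47.6%) and 408 for wounding (40.2% higher, against 46.9%). The causes of these changes were not tested. The prior degrees of freedom of the fit were infinite in the main setting, 19.7 with the median over probe sets and 9.99 with no filter. Quantile normalization, median centring and cyclic loess moved the median of all genes by less than 0.1 and turned the direction of none of the named genes that had been called. The balance of the calls did depend on scaling. Higher genes made up 47.6% of the MMP-8 calls, but 52.4% with quantile normalization and 51.2% with cyclic loess. For wounding they made up 46.9%, 51.7% and 51.4% in the same order. Median centring gave 47.6% for the MMP-8 effect and 48.8% for wounding.

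Directions turned for some called genes. With the median over probe sets, the MMP-8 effect became -0.36 for ITGB8 and 0.20 for NRG1, and wounding became 0.14 for MMP28, -0.23 for TAGLN, 0.20 for TNFRSF10B, 0.17 for ERBB3, -0.26 for ADAMTS6 and 0.092 for COL1A1. Without possibly cross-hybridizing probe sets, the MMP-8 effect became -0.011 for MCM5, 0.18 for IDI1 and 0.32 for NRG1, wounding became 0.19 for TMT1A, and the difference of responses became 0.87 for FGF18. With a constant of 1 it became -0.039 for LAMA2. Each of these alternatives read other probe sets for these genes. Of the values of single named genes under the alternatives of scaling, probe set choice, constant, filter and trend, 1731 kept their side of the threshold, 211 no longer passed and 6 newly passed. Most of those lost were lost without the trend, where no gene passed. Of the medians of the gene lists, 310 moved by less than the spread of their 2 contrasts, 74 moved by more and 0 of those outside the random range changed sign.

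The additive fit takes the line differences within each state and the wounding differences within each line. No pairing by replicate was possible beyond that, because each group has 1 array and the groups share fewer than 2 replicate numbers. Leaving out an array would leave no residual degrees of freedom. Signal over background limits the dim genes, since 4383 of 13640 genes stayed under an intensity of 100.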

Other observations

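The 4 gene lists used here were chosen after the genes that changed most with wounding had been seen, so their direction over all members is not independent evidence. The tests on members outside the 150 most raised and 150 most lowered genes were set before their values were seen.

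Genes of ribosome biogenesis were higher after wounding in both lines, with a median of 0.43, and of 39 members 30 rose and 1 fell. RRP12 rose by 0.86, RRS1 by 0.84 and POLR1G by 0.77. The hypothesis of a rise shared by the group predicts that members outside the most changed genes also lie above random lists. The 33 such members had a median of 0.36, at percentile 100. ERK pathway output genes had a median of 0.41, with 12 rising and 1 falling of 16, among them EPHA2 (1.02) and EPHA4 (0.88). The 9 members outside the most changed genes had a median of 0.26, at percentile 99.6, with 5 rising and 1 falling. The prediction held for both groups in these arrays. For ERK output the members left are not all fresh, since EGR1, IER3, SPRY2, SPRY4 and CCND1 also stand in lists fixed in advance. Of those lists, immediate early genes (percentile 76.4) and EGFR ligands and receptors (percentile 78.5) lay inside the random range. Cell cycle genes, which hold CCND1, lay above it (percentile 99.8).

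Genes known to be induced by glucocorticoids were lower after wounding, with a median of -0.49, and of 14 members 9 fell and 0 rose. TSC22D3 fell by 1.24, KLF9 by 1.10 and FKBP5 by 0.50. The 10 members outside the most changed genes had a median of -0.24, at percentile 0.1, which is consistent with a shared fall. DUSP1 and NFKBIA, which also stand in the immediate early and inflammatory lists, were not among these 10. ERRFI1 (-0.13) and ANGPTL4 (0.24) were, and they also stand in the EGFR and VEGF lists. The medium contained hydrocortisone, per the labels, and whether it was changed at wounding is not given in the sources used here. FOXO targets had a median of -0.40, with 1 rising and 9 falling of 15, among them FBXO32 (-1.31) and TNFSF10 (-1.25). The 11 members outside the most changed genes had a median of -0.15, at percentile 4.22, inside the central 95% of random lists, so a fall shared by that group did not pass its test. Of these members, BNIP3, SESN1 and GADD45A also stand in the hypoxia and p53 lists.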
